A study of Danio rerio with 8 samples.

How the data were processed

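Nuclei came from sections of spinal cord, 3 mm long, of adult wild-type zebrafish, from 50 animals pooled per time point, per the labels. Libraries were made with the 10x Genomics 3' kit (version 3.1) and sequenced on a NovaSeq instrument. The deposited matrices hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger 6.0.0, per the file headers and the submitters' processing notes, on genome build GRCz11 with the Lawson transcriptome annotation, per the series text. The counts are of all barcodes that Cell Ranger called as nuclei, before any correction of free RNA. The submitters' processing notes also name Seurat 4.1.1 and R 4.2.1, and the series text states that 58,973 nuclei were left after correction with DecontX and removal of doublets and poor nuclei. DecontX was not used here, so that free RNA stayed in the counts, and free RNA was measured through erythroid nuclei. Their levels are compared in CPM, which does not allow for the lower depth of these nuclei. The matrices used here held 74,891 barcodes and 192,654,970 UMIs. Cell names are those given here and not the study's, and differences from the study can come from that.

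All steps below were computed from these counts with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0). Genes are named by the symbols in the files. A symbol shared by several gene identifiers, as 216 symbols were, was kept as separate genes. Genes listed by all files numbered 36,350, and the 1 further gene of the larger list was left out. Barcodes with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs passed, which left 73,913. In each library the expected number of doublets, 0.8% per 1000 barcodes, was then removed, taking the barcodes with the highest share of simulated doublets among their neighbours (1 simulated doublet per barcode). This took out 5767 barcodes (7.8%) and left 68,146 nuclei. The gene with the highest share of a library's counts, CR383676.1, took from 4.62% to 9.24%.

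Nuclei were clustered on 2000 variable genes, 40 principal components and 20 neighbours with the Leiden algorithm at resolution 2.0, without integration across libraries. A cluster was named from marker genes fixed beforehand. The scoring rule was not fixed beforehand. It asked for at least 3 markers and 25% of a class's markers on (at least 20 CPM and 25% of the highest cluster), and a median log2 fold of 0.5 over other clusters with 20 CPM added. It also asked for a lead of 15 percentage points over the next class or, in its place, a marker of the class and none of another among the 10 leading genes, by which cluster 19 was named. A cluster with more markers of another class than of its own among these 10 genes stayed without a name, as did very shallow clusters with no own marker there. Clusters 14 and 42, which scored highest for lymphocytes and for microglia, were left without a name in this way. Clusters without a name enter whole libraries and totals only. The 1 cluster named as lymphocytes came mainly from the batch with the shorter gene list and was not compared. Classes were compared where every library held at least 20 nuclei.

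Counts were summed per library and class, and libraries, not nuclei, were the replicates. Uninjured, 1, 3 and 6 wpi were fitted together with edgeR's quasi-likelihood test (TMM factors, filterByExpr, all 8 libraries, Benjamini-Hochberg adjustment at 0.05). Each time was compared with uninjured cord and with the time before it. Log2 fold changes carry their standard error, and levels with an SD between the 2 libraries of a group are CPM scaled by the TMM factors. Within-batch differences, levels in erythroid nuclei and fibroblasts beside a class, and figures use CPM of the class total without these factors. The test, the gene lists, the markers and the rule for named genes were chosen before the data were examined. That rule takes genes called with an absolute log2 fold change of at least 1, both injured libraries on the same side of both uninjured ones, a mean of at least 50 CPM in the higher group, at least 20% of the level of the highest class, and a symbol that is no clone name. It takes up to 10 genes per direction in neurons and 6 in the other classes, by the size of the change. Genes of the fixed lists are named besides. A gene that met the rule in microglia is not reported here. The 24 gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a class and contrast, over 288 tests in 4 classes and 3 contrasts. With the preset correlation 162 of the 288 passed. With an estimated correlation the calls of 3 held, namely regeneration-associated genes in neurons at 1 and 3 wpi and neurogenesis factors in neurons at 1 wpi. Members of a list are counted as called over all genes tested and, beside that, adjusted over the list alone.

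Class shares were tested with edgeR on the numbers of nuclei, with library totals as offsets, and with an exact permutation test of the F statistic over the 105 partitions of the libraries into pairs, which was also used for the excitatory and cycling shares. All tests are two-sided except those of F, which takes large values only. Comparing 2 with 2 libraries allows no exact p under 0.05, which is why partitions over all 4 groups were used. Intervals of shares are 95% Wilson intervals. Nuclei were thinned to 1000 UMIs for the cycling share.

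The count test was tested on simulated data made from the real means, with 200 genes changed at 1 wpi. The changed genes were drawn from those with a mean of at least 20 CPM, so that recovery at lower levels was not measured. All libraries were drawn from 1 common mean per gene, without batches. In neurons it recovered 16.4% of genes changed 2-fold, 91% of those changed 4-fold and 98.5% of those changed 8-fold, with 12 false calls among 149 in 21,790 genes. In ependymo-radial glia it recovered 0%, 76.1% and 93.9% (12 false among 125 calls in 17,561 genes), in oligodendrocytes 1.5%, 67.2% and 98.5% (6 among 117 in 17,496 genes), in microglia and macrophages 1.5%, 64.2% and 92.4% (9 among 114 in 14,723 genes), and in whole libraries 0%, 40.3% and 90.9% (9 among 96 in 25,927 genes). At this depth and number of libraries changes near 2-fold were therefore mostly missed.

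The alternatives tried were DESeq2's size factors, DESeq2's Wald test, no filter on low counts, the replicate number as a block, only the 4 libraries of a contrast, nuclei with at least 1000 UMIs, no doublets removed, clusters at resolution 1.0, genes with at least 20% of the level of the highest class, thinned counts, and each library left out in turn. Added after the data were seen were the batch of the gene list length as a term, leaving out both libraries of the shorter list, leaving out nuclei over 20,000 UMIs, and shares among named classes only. Genome coordinates were not used here.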

Results

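RNA in single nuclei was measured in the spinal cord of adult zebrafish, a fish that rebuilds a severed cord, in uninjured animals and at 1, 3 and 6 weeks after a complete transection (wpi). Each of the 4 groups held 2 libraries made from separate pools of animals. Total counts were 20,327,907 and 23,406,399 UMIs (unique molecular identifiers, which count captured RNA molecules) in the uninjured libraries, 41,167,153 and 21,773,310 at 1 wpi, 14,597,194 and 26,386,975 at 3 wpi, and 20,229,132 and 24,766,900 at 6 wpi. The median barcode held from 1247 UMIs in 3 wpi replicate 1 to 2106 in 6 wpi replicate 2. The 68,146 nuclei kept were clustered and the clusters were named from marker genes. Neurons, ependymo-radial glia (the glia that line the central canal), oligodendrocytes, microglia with macrophages, oligodendrocyte precursors, fibroblasts and erythroid nuclei were present in every library, and all of these names are used in the sense of "neuron-like" and so on. Clusters left without a name held 37.3% and 30.9% of the uninjured nuclei, 38.3% and 25.5% at 1 wpi, 13.4% and 19.8% at 3 wpi, and 31.5% and 25.2% at 6 wpi.

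The 2 libraries of each group were counted as replicates, as the series text describes them. They differed by more than counting noise, as preparations made apart do, with a chi-square per degree of freedom of 23.8 in uninjured cord, 111 at 1 wpi, 29.2 at 3 wpi and 45.0 at 6 wpi. Uninjured replicate 1 and 1 wpi replicate 1 listed 1 gene fewer than the other libraries, which was taken here as a sign of 2 processing batches that the labels do not state. In log2 CPM (counts scaled to the same total in every library) across genes, which are not independent replicates, 1 wpi replicate 1 correlated more closely with uninjured replicate 1 (r = 0.969) than with 1 wpi replicate 2 (r = 0.883). Values at 1 wpi are therefore also given within each of these batches, as the difference in log2(CPM + 1) of 1 library at 1 wpi from 1 uninjured library, whereas 3 and 6 wpi have libraries in the batch of the longer gene list only. Clusters 11, 35, 40 and 46 of the neurons, 20 and 34 of the ependymo-radial glia, 8 of the oligodendrocytes and 13 of the microglia held mainly nuclei of the batch of the shorter gene list. The remaining clusters of each class held mainly those of the other libraries. Each comparison with uninjured cord asks which genes differ in a cell class at that time after transection.

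Neurons at 1 wpi held more RNA of genes known from growing axons. The growth cone gene gap43 stood at 146 ± 3.29 CPM (SD, n = 2) against 22.6 ± 3.34 in uninjured neurons (log2 fold change 2.69 ± 0.26 SE, adjusted p = 0.0131). The stathmins stmn4 and stmn4l, which bind tubulin, rose from 82.2 ± 7.91 to 204 ± 8.99 CPM (1.31 ± 0.19, adjusted p = 0.0489) and from 42.1 ± 5.71 to 138 ± 2.5 CPM (1.71 ± 0.16, adjusted p = 0.0103). Of 26 regeneration-associated genes 5 rose over all genes tested and 16 when adjusted over the list alone. The 5 were gap43, stmn4, the transcription factor jun (2.70 ± 0.25), the cytokine signalling inhibitor socs3b (2.85 ± 0.30) and the cell adhesion gene l1camb (0.89 ± 0.12). The list as a whole rose with camera adjusted p = 1.13e-19, and adjusted p = 0.0110 with an estimated correlation. Of 21 neurogenesis factors 2 rose, sox4a (2.17 ± 0.31) and the tubulin gene tubb5, and 5 rose adjusted over the list alone (camera adjusted p = 3.42e-08, and adjusted p = 0.0345 with an estimated correlation).

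Altogether 42 genes were higher and 5 lower in neurons at 1 wpi among 22,207 tested, and 8 and 3 of them met the naming rule. Among those 8 the largest rises were those of uts2a, a urotensin peptide gene (3.72 ± 0.24, adjusted p = 0.00524), tubb5 (3.38 ± 0.28, adjusted p = 0.00822) and the metalloprotease gene adam8b (3.15 ± 0.39, adjusted p = 0.0309). The dynamin gene dnm3a rose by 2.66 ± 0.24 (adjusted p = 0.0101) and the chromatin factor gene baz2ba by 1.14 ± 0.14, from 295 ± 2.06 to 651 ± 97.1 CPM (adjusted p = 0.0309). Lower were nrn1la, which fell by 1.24 ± 0.17 on the log2 scale from 101 ± 12.3 to 42.4 ± 5.47 CPM, the mitochondrial coactivator gene ppargc1b (-1.12 ± 0.15) and the phosphodiesterase gene pde10a (-1.06 ± 0.14), with adjusted p of 0.0388 to 0.0431. All 11 genes had the same sign in both batches, which the naming rule all but fixes by asking for the same side in every library. The sizes were 2.6 for gap43 in the batch of the shorter gene list and 2.83 in the other, and -0.89 and -1.41 for nrn1la. Clusters led by 2 of these genes hold part of the class, uts2a leading cluster 11 and nrn1la cluster 4. Erythroid nuclei, which should lack neuronal RNA and so show the free RNA in the droplets, held gap43 at 56.2% of its neuronal level at 1 wpi, stmn4 at 64.8%, stmn4l at 37.8%, dnm3a at 50.5% and l1camb at 42.5%. They held uts2a (114%), adam8b (118%), tubb5 (278%), socs3b (144%) and sox4a (208%) above the neuronal level in CPM, from 9 to 111 UMIs. Erythroid nuclei were shallow, at a median of 977 UMIs, so that free RNA can take a larger share of their counts. These percentages, here and below, do not compare levels per nucleus. By class, uts2a stood at 96.1 CPM in neurons against 31.1 in ependymo-radial glia, 24.2 in oligodendrocytes and 34.8 in microglia, whereas tubb5 stood at 124, 146, 123 and 171 CPM. In uninjured cord erythroid nuclei held nrn1la at 116% and pde10a at 131% of the neuronal level.

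edgeR called 0 genes in 5 lists of synaptic transmission and transmitter identity in neurons at 1 wpi. At an unadjusted p under 0.05 were 1 of 14 genes of glutamatergic identity (0 by DESeq2), 2 of 18 of GABAergic and glycinergic identity (1 by DESeq2), 13 of 24 glutamate receptors (1 by DESeq2) and 7 of 24 GABA and glycine receptors (0 by DESeq2). Of all 22,207 genes tested 2041 were, a lower share than in the 2 receptor lists. The 0 calls therefore do not show that receptor RNA was unchanged in neurons. Among 29 synaptic vesicle genes the median log2 fold change was -0.07 (camera adjusted p = 0.175), and 0 were called over all genes or over the list alone (4 at an unadjusted p under 0.05, 0 by DESeq2). The vesicle genes sv2bb and vamp4 had log2 fold changes of -0.07 (adjusted p = 0.994) and 0.30 (adjusted p = 0.804). The vesicular glutamate transporter genes slc17a6a and slc17a6b had 0.30 (adjusted p = 0.868) and -0.05 (adjusted p = 0.997), and the glycine transporter gene slc6a5 had -0.80, at 197 against 342 CPM (adjusted p = 0.178). The injury-induced transcription factor atf3 had 44.9 against 5.62 CPM (3.00 ± 0.44, adjusted p = 0.0595). Of 13 motor neuron genes 1 rose, the intermediate filament gene prph (2.06 ± 0.25, adjusted p = 0.0309), at camera adjusted p = 0.770 for the list.

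At 3 and 6 wpi edgeR called 0 genes in neurons, with 2114 and 1558 genes at an unadjusted p under 0.05 and 133 and 142 calls by DESeq2. With the replicate number as a block edgeR did call genes at these times, as given below. The level of gap43 was 67.3 CPM at 3 wpi (1.57, adjusted p = 0.258) and 33.3 CPM at 6 wpi (0.56, adjusted p = 0.729). At 3 wpi 13 of the 26 regeneration-associated genes rose adjusted over the list alone (camera adjusted p = 6.08e-11, and adjusted p = 0.0363 with an estimated correlation). At 6 wpi 5 did (camera adjusted p = 7.68e-07, and adjusted p = 0.0587 with an estimated correlation). Of 38 motile cilia genes 16 rose in the neuron class at 3 wpi and 27 at 6 wpi adjusted over the list alone. The list had camera adjusted p = 5.11e-18 and 1.17e-30, and adjusted p = 0.179 and 0.0599 with an estimated correlation. It also rose in ependymo-radial glia, as given below. Between 1 and 3 wpi and between 3 and 6 wpi the test called 0 genes (1573 and 787 at an unadjusted p under 0.05, and 35 and 1 by DESeq2). The count of 47 at 1 wpi became 0 without uninjured replicate 1 or without uninjured replicate 2, 13 without 1 wpi replicate 2, 30 without 1 wpi replicate 1 and 17 or 18 without any 1 library of 3 or 6 wpi. The count at 6 wpi became 3 and 2 without 1 wpi replicates 1 and 2, where a group left with 1 library is assumed to vary like the others. The count at 1 wpi was also 0 with only the 4 libraries of the contrast, 0 without both libraries of the shorter gene list, 78 among genes with at least 20% of the level of the highest class, and with the batch as a term 82 genes were higher and 23 lower.

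**Figure D1:**
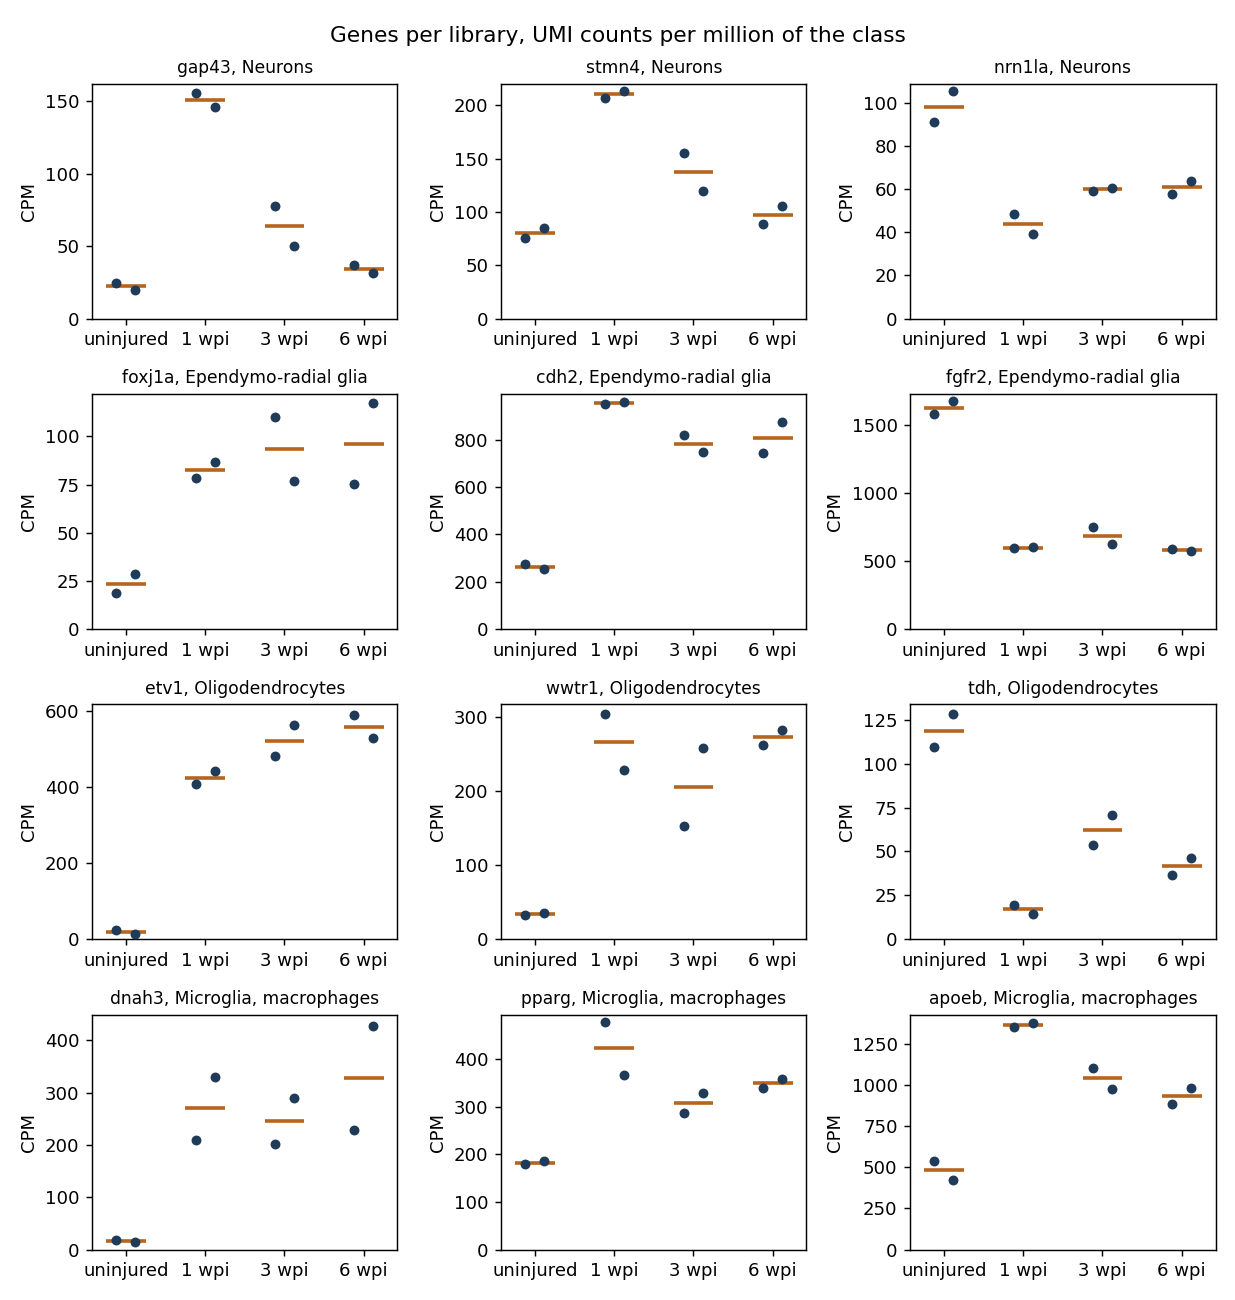
Level of 12 genes in their cell class in each library (vertical axes, CPM of the class total without TMM factors; horizontal axis, group). Points are libraries and bars group means, and gap43 in neurons lay at 155 and 146 CPM at 1 wpi against 24.7 and 19.6 in uninjured cord.

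Ependymo-radial glia held more RNA of cilia genes at all 3 times after transection. foxj1a, the master regulator of motile cilia, stood at 82.8, 96.7 and 93.9 CPM at 1, 3 and 6 wpi against 24.4 in uninjured cord (log2 fold changes 1.73 ± 0.34, 1.95 ± 0.35 and 1.91 ± 0.34, adjusted p from 0.0323 to 0.0466). The axonemal dynein gene dnah5 was at 293, 314 and 287 CPM against 88.6. Of 39 motile cilia genes 13, 17 and 12 rose over all genes at 1, 3 and 6 wpi, and 35 at each time adjusted over the list alone, with median log2 fold changes of 1.68, 1.81 and 1.64. The list rose with camera adjusted p = 5.98e-28, 9.17e-33 and 4.75e-34, and with an estimated correlation adjusted p = 0.108, 0.121 and 0.102, so that no call held. The tektin gene tekt4 (2.95, 3.24 and 3.01) and cfap43 (2.21, 2.46 and 1.98), both of the ciliary axoneme, were among the members that rose at each time. Cluster 7 of this class, with cfap57, ccdc175 and runx2a among its leading genes, held 0% and 0.038% of the uninjured nuclei, 0.123% and 3.93% at 1 wpi and from 5.47% to 7.67% at 3 and 6 wpi. Cluster 20 held 2.81% of uninjured replicate 1 and 6.65% of 1 wpi replicate 1, and a rise of cilia genes within single clusters was not tested. Within batches at 1 wpi foxj1a differed by 2.03 and 1.57 and dnah5 by 2.09 and 1.54. Erythroid nuclei held foxj1a at 41.8%, 9.8% and 65.8% of the glial level at 1, 3 and 6 wpi, and dnah5 at 24.0%, 51.6% and 36.0%. In tests added after the data were seen, the motile cilia list also rose in oligodendrocyte precursors and fibroblasts at 3 and 6 wpi. In precursors its median was 0.96 and 1.11 (camera adjusted p = 0.000602 and 1.23e-05, and adjusted p = 0.318 and 0.315 with an estimated correlation). In fibroblasts it was 1.21 and 1.37 (camera adjusted p = 0.00157 and 0.00108, and adjusted p = 0.694 and 0.479 with an estimated correlation). At 1 wpi the list passed in neither class.

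Some cholesterol synthesis genes were lower in these glia at 1 and 3 wpi, and from 1 to 3 FGF signalling genes at each time. Of 24 cholesterol synthesis genes 5 fell at 1 wpi, 5 at 3 wpi and 0 at 6 wpi over all genes, and 14, 15 and 0 adjusted over the list alone (camera adjusted p = 5.94e-14, 2.92e-12 and 0.000407, and adjusted p = 0.108, 0.131 and 0.438 with an estimated correlation). At 6 wpi 3 members had an unadjusted p under 0.05, and DESeq2 called 0. The early enzyme gene hmgcs1 fell by 1.66 ± 0.31 on the log2 scale at 1 wpi, from 112 to 35.6 CPM (adjusted p = 0.0404), and had 89.1 CPM at 6 wpi (adjusted p = 0.724). The later enzyme genes msmo1 and ebp fell by 2.29 ± 0.34 and 2.69 ± 0.43 at 1 wpi. Of 17 FGF targets and ligands 1, 2 and 3 fell at 1, 3 and 6 wpi, and 6, 9 and 8 adjusted over the list alone (camera adjusted p = 1.64e-05, 9.04e-06 and 1.93e-08, and adjusted p = 0.108, 0.121 and 0.0693 with an estimated correlation). The receptor gene fgfr2 fell from 1677 to 599, 708 and 566 CPM (-1.49 ± 0.18, -1.25 ± 0.18 and -1.57 ± 0.18, adjusted p from 0.0121 to 0.0162). The feedback inhibitor gene spry1 fell by 2.02 ± 0.35 at 3 wpi and 2.01 ± 0.34 at 6 wpi, whereas etv5a fell at 6 wpi (-1.53 ± 0.28). Within batches at 1 wpi fgfr2 differed by -1.42 and -1.47 and hmgcs1 by -1.63 and -1.55. In uninjured cord erythroid nuclei held fgfr2 at 15.9%, hmgcs1 at 43.5%, ebp at 53.7% and msmo1 at 95.4% of the glial level.

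The genes cdh2 and notch1b were higher in these glia at each time. The N-cadherin gene cdh2 rose from 271 to 956, 811 and 791 CPM (1.82 ± 0.18, 1.58 ± 0.18 and 1.54 ± 0.18, adjusted p from 0.00715 to 0.0119). The receptor gene notch1b rose from 61.8 to 149, 213 and 161 CPM (1.27 ± 0.25, 1.79 ± 0.25 and 1.39 ± 0.25). Of 24 Notch pathway genes 2, 2 and 1 rose over all genes, and 4, 5 and 3 rose and 0, 0 and 1 fell adjusted over the list alone. The list had camera adjusted p = 7.51e-05, 0.00402 and 0.0413, and adjusted p = 0.108, 0.131 and 0.370 with an estimated correlation. Of 19 glial bridging genes cdh2 rose at each time and the intermediate filament gene vim at 3 wpi (1.25 ± 0.23, adjusted p = 0.038), with camera adjusted p = 0.0016, 0.00268 and 0.00492, and adjusted p = 0.108, 0.121 and 0.133 with an estimated correlation. The related gene gfap had 1560, 2440 and 1549 against 1101 CPM and was not called (adjusted p = 0.523, 0.132 and 0.594). Of 35 extracellular matrix genes 6 rose and 1 fell at 1 wpi (camera adjusted p = 0.0451, and adjusted p = 0.387 with an estimated correlation). Among them were the tenascin gene tnc (1.30 ± 0.23), the laminin gene lamb2 (2.03 ± 0.30) and the fibronectin gene fn1a (2.3 ± 0.43), whereas the basement membrane collagen gene col4a1 fell (-1.91 ± 0.35). At 3 wpi vim stood at 891 CPM in oligodendrocytes against 178 in these glia, and erythroid nuclei held it at 60% of the glial level. Fibroblasts held tnc at 152 CPM at 1 wpi against 79.2 in these glia, and erythroid nuclei held tnc at 58.1% and lamb2 at 33.1% of the glial level. Fibroblasts held fn1a at 193 CPM at 1 wpi and col4a1 at 1176 CPM in uninjured cord, and erythroid nuclei held fn1a and col4a1 at 84.0% and 98.7% of the glial level. Erythroid nuclei held cdh2 at 29.9%, 66.1% and 51.7% of the glial level at 1, 3 and 6 wpi and notch1b at 52.3%, 33.4% and 53.2%. Within batches at 1 wpi cdh2 differed by 1.78 and 1.92, notch1b by 0.92 and 1.62 and fn1a by 1.25 and 3.09.

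Over all 18,173 genes tested 234 were higher and 97 lower at 1 wpi, 247 and 51 at 3 wpi, and 167 and 24 at 6 wpi, of which 115 and 52, 121 and 30, and 86 and 18 met the naming rule. The annexin gene anxa2a (5.76 ± 0.66, adjusted p = 0.011), the metalloprotease gene adamts8a (4.43 ± 0.42, adjusted p = 0.00715) and the complement gene c7a (4.14 ± 0.28, adjusted p = 0.0031) rose most at 1 wpi among genes that met the rule. They were followed by tubb5 (3.40 ± 0.31), the glutamate transporter gene slc1a3b (3.37 ± 0.47) and cyp27c1 (3.33 ± 0.39), and adamts8a went from 8.67 ± 0.789 to 185 ± 35.2 CPM. At 3 wpi the transcription factor gene runx2a rose from 27.5 ± 6.19 to 358 ± 17.9 CPM (3.73 ± 0.30, adjusted p = 0.00511). The ligand gene wnt4b rose from 9.43 ± 3.86 to 119 ± 15 CPM (3.58 ± 0.34, adjusted p = 0.00616), beside the receptor gene met (3.48 ± 0.32). At 6 wpi the hormone gene pth1a rose from 1.65 ± 0.0392 to 60.4 ± 7.47 CPM (5.16 ± 0.67, adjusted p = 0.0157). Of the genes that fell at 1 wpi and met the rule, the thyroid hormone activating enzyme gene dio2 went from 73.7 ± 27.1 to 14.2 ± 5.14 CPM (-2.41 ± 0.47, adjusted p = 0.0447). The threonine dehydrogenase gene tdh fell from 110 to 20.7 CPM (-2.40 ± 0.36) and the citrate transporter gene slc13a5a from 82.6 ± 4.16 to 18.7 ± 2.00 CPM (-2.15 ± 0.30). The genes c1qtnf12, ppp1r1b and dicp1.1 fell by 2.18, 2.08 and 1.89 on the log2 scale. The clock gene per3 fell by 2.48 ± 0.28 at 3 wpi and the carbonic anhydrase gene ca6 by 1.51 ± 0.24 at 6 wpi. The 12 named genes at 1 wpi had the same sign in both batches, as the naming rule asks, with median sizes of 2.66 and 2.62.

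The genes runx2a and c1qtnf12 lead clusters 7 and 10 of this class, and fgfr2 and ca6 lead clusters 12 and 34. Their values can therefore depend on how the nuclei are spread over these clusters, which was not tested. Fibroblasts held anxa2a at 165 and c7a at 480 CPM at 1 wpi, above the glia. Erythroid nuclei held anxa2a at 31.0%, c7a at 41.6%, adamts8a at 21.3%, slc1a3b at 11.8%, tubb5 at 236%, tdh at 93.4% and, at 3 wpi, runx2a at 16.6%, wnt4b at 48.8% and per3 at 120% of the glial level. At 3 wpi the median log2 fold change of all genes was -0.11. The test called 0 genes between 1 and 3 wpi (1078 at an unadjusted p under 0.05, 3 by DESeq2) and 0 between 3 and 6 wpi (439, and 1 by DESeq2). Without uninjured replicate 1 the counts of 331, 298 and 191 became 2 each, and without uninjured replicate 2 they became 0, 27 and 16. Leaving out 1 wpi replicate 1 or 2, 3 wpi replicate 1 or 2, or 6 wpi replicate 1 or 2 gave 320, 111, 49, 48, 200 and 166 at 1 wpi, 559, 492, 0, 32, 221 and 169 at 3 wpi, and 323, 267, 38, 42, 109 and 12 at 6 wpi. With only nuclei of at least 1000 UMIs the counts were 67, 0 and 1, and with only the 4 libraries of the contrast 0, 661 and 20. Without both libraries of the shorter gene list they were 21, 107 and 50, and with the batch as a term 773 at 1 wpi and 298 at 6 wpi.

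**Figure D2:**
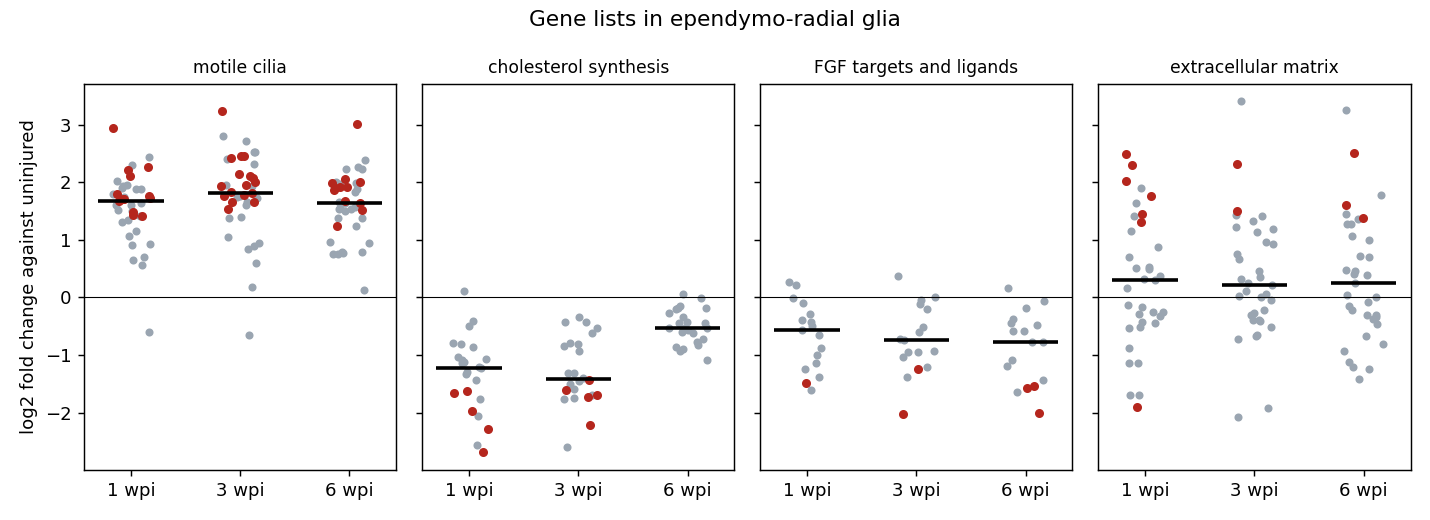
Log2 fold change against uninjured cord (vertical axis) of the members of 4 gene lists in ependymo-radial glia at 1, 3 and 6 wpi (horizontal axis). Points are genes, red where the adjusted p was under 0.05, and black lines are medians, which for motile cilia lay at 1.68, 1.81 and 1.64.

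Oligodendrocytes held more RNA of the regulator genes etv1 and wwtr1 at every time. The ETS family gene etv1 stood at 447 ± 63.0, 553 ± 71.6 and 540 ± 20 CPM at 1, 3 and 6 wpi against 17.1 ± 6.09 in uninjured cord (log2 fold changes 4.72 ± 0.32, 5.03 ± 0.33 and 5.0 ± 0.33, adjusted p = 0.00272, 0.00252 and 0.00264). The gene wwtr1, a coactivator of the Hippo pathway, stood at 277, 218 and 264 CPM against 32.7 (3.08 ± 0.32, 2.73 ± 0.32 and 3.01 ± 0.32). The gene icn, a calcium-binding protein gene, rose from 1.74 ± 1.62 to 119 ± 10.6 CPM at 1 wpi (5.94 ± 0.59, adjusted p = 0.0123). The myelin basic protein gene mbpb rose at 1 wpi, from 204 to 609 CPM (1.58 ± 0.26, adjusted p = 0.0347). It was the 1 of 16 myelin genes that rose over all genes, and 2 rose adjusted over the list alone (camera adjusted p = 0.00037, and adjusted p = 0.208 with an estimated correlation). Lower at 1 wpi were the transporter gene slc6a22.1 (-2.80 ± 0.36), tdh (-2.67 ± 0.30, from 114 ± 21.9 to 17.9 ± 2.40 CPM) and auts2b (-2.58). The fall of tdh was similar in ependymo-radial glia, from 110 to 20.7 CPM, and whether it arose within oligodendrocytes was not tested.

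Across 18,181 genes tested 140 were higher and 43 lower at 1 wpi, 49 and 2 at 3 wpi, and 57 and 0 at 6 wpi (1558 at an unadjusted p under 0.05 and 193 calls by DESeq2 at 6 wpi). Of these 71 and 21, 18 and 1, and 23 and 0 met the naming rule. Beside icn and etv1 the hexokinase gene hk2 (4.46 ± 0.73, 602 ± 443 against 27.2 ± 4.78 CPM), macc1 (3.86 ± 0.45), mindy4b (3.80) and nlrc3 (3.72) rose most at 1 wpi among genes that met this rule. The leukocyte gene lsp1 and the neuropeptide receptor gene vipr1a rose by 3.71 and 3.41 at 3 wpi and by 3.81 and 3.96 at 6 wpi. The peripheral myelin protein gene pmp22b rose from 8.52 ± 1.96 to 120 ± 17.5 CPM at 6 wpi (3.79 ± 0.29, adjusted p = 0.0056). Of 19 glial bridging genes 2 rose at 1 wpi, wwtr1 and the growth factor receptor gene egfra (1.74 ± 0.30), and wwtr1 at 3 and 6 wpi, with camera adjusted p = 0.0894, 0.00112 and 0.0023, and adjusted p = 0.252, 0.277 and 0.203 with an estimated correlation. Of 20 immediate early genes the AP-1 subunit genes fosl1a (2.19 ± 0.35) and fosl2 (1.98 ± 0.33) rose at 1 wpi (camera adjusted p = 0.366 for the list). The lipid carrier gene apoeb rose by 4.47, 2.63 and 2.69, and erythroid nuclei held it at 162%, 258% and 131% of the oligodendrocyte level. At 1 wpi apoeb stood at 184 CPM in oligodendrocytes against 44.2 in neurons, 81.4 in ependymo-radial glia and 1365 in microglia.

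Glutamate receptor genes, which belong to neurons and precursors, were lower as a list in this class at 1 wpi. Of 23 members 0 fell over all genes and 19 adjusted over the list alone, at a median log2 fold change of -1.06 (camera adjusted p = 1.56e-12, and adjusted p = 0.252 with an estimated correlation). Of the 23 members 20 had an unadjusted p under 0.05 and DESeq2 called 11. Of 17 neuron markers the median was -0.87 (camera adjusted p = 6.1e-07, and adjusted p = 0.281 with an estimated correlation), and neurons held 48.1% and 47.0% of the UMIs of the uninjured libraries and 32.1% and 35.1% at 1 wpi. At 6 wpi neurons held 33.1% and 37.0%, but 26 genes highest in neurons then had a median of only -0.22 in oligodendrocytes, against -0.77 at 1 wpi. All 12 named genes had the same sign in both batches at 1 wpi, as the naming rule asks, with median sizes of 2.82 and 3.50. Within the batches etv1 stood at 4.04 and 5.02, wwtr1 at 3.19 and 2.64 and mbpb at 1.24 and 1.67. Clusters 15 and 41 are led by etv1, cluster 15 also by icn and cluster 8 by macc1, and mbpb is among the leading genes of cluster 41. Cluster 15 held 0% and 0.025% of the uninjured nuclei, 0.1% and 1.59% at 1 wpi and from 2.70% to 6.04% at 3 and 6 wpi. Cluster 1, the largest of the class, held 15% of uninjured replicate 2, 11.9% of 1 wpi replicate 2 and from 9.40% to 13.8% at 3 and 6 wpi, and cluster 8 held 9.77% of uninjured replicate 1 and 11.5% of 1 wpi replicate 1. At 1 wpi erythroid nuclei held etv1 at 15%, macc1 at 11.2%, wwtr1 at 20.7%, mbpb at 28.7%, hk2 at 35.3%, icn at 34.6%, egfra at 141% and fosl2 at 170% of the oligodendrocyte level, and fibroblasts held icn at 187 CPM. The test called 0 genes between 1 and 3 wpi (1181 at an unadjusted p under 0.05, 20 by DESeq2) and 0 between 3 and 6 wpi (498, and 0 by DESeq2). Without either uninjured library the counts of 183, 51 and 57 became 1 each. Leaving out 1 wpi replicate 1 or 2, 3 wpi replicate 1 or 2, or 6 wpi replicate 1 or 2 gave 447, 45, 34, 30, 51 and 36 at 1 wpi, 206, 171, 7, 1, 13 and 14 at 3 wpi, and 138, 130, 12, 12, 3 and 6 at 6 wpi. There were 5 calls between 1 and 3 wpi without 1 wpi replicate 2. With only the 4 libraries of the contrast the counts were 0, 560 and 36, with only nuclei of at least 1000 UMIs 53 at 1 wpi, and with the batch as a term 973 at 1 wpi.

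Microglia and macrophages, the phagocytes of the cord, held more RNA of the lipid genes apoeb, pparg and g0s2 at 1 wpi. The apolipoprotein E gene apoeb rose from 485 to 1427 CPM (log2 fold change 1.55 ± 0.20, adjusted p = 0.0325) and the lipid-sensing receptor gene pparg from 183 to 441 CPM (1.27 ± 0.19, adjusted p = 0.0435). The gene g0s2, an inhibitor of triglyceride breakdown, rose from 1.63 ± 0.569 to 116 ± 66.9 CPM (6.17 ± 0.79, adjusted p = 0.0334). apoeb and pparg were the 2 of 26 phagocyte lysosome and lipid genes that rose over all genes, and 7 rose adjusted over the list alone (camera adjusted p = 2.17e-08, and adjusted p = 0.157 with an estimated correlation). The dynein gene dnah3 rose from 16.3 ± 2.97 to 283 ± 94.1 CPM at 1 wpi (4.08 ± 0.44, adjusted p = 0.017) and stood at 331 ± 141 CPM at 6 wpi (4.31 ± 0.45, adjusted p = 0.0364). The ion channel gene trpv1 was at 170 ± 44.9 CPM at 1 wpi and 93.9 ± 1.94 CPM at 6 wpi against 14.9 ± 1.94.

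Over 15,376 genes tested 42 were higher and 9 lower at 1 wpi, 0 and 0 at 3 wpi (1556 at an unadjusted p under 0.05, 52 by DESeq2) and 9 and 0 at 6 wpi (1438, and 45 by DESeq2). Of these 32 and 8 at 1 wpi and 5 and 0 at 6 wpi met the naming rule. Further rises at 1 wpi were those of the guidance receptor gene robo4 (4.92), antxr1c (3.89) and tubb5 (3.70 ± 0.27). At 6 wpi the phosphodiesterase gene pde4ba rose from 388 ± 76.9 to 2146 ± 315 CPM (2.46 ± 0.29, adjusted p = 0.0414), beside the cytokine gene tnfsf10l (2.11 ± 0.27) and DOCK4 (1 of many) (1.85 ± 0.23), whose reads could be split between its copies. Among the largest falls at 1 wpi were those of nrg1 (-1.50 ± 0.24), neto1l (-1.44), syngap1b (-1.40), dlgap3 (-1.28) and ank1a (-1.23). Erythroid nuclei of uninjured cord held ank1a at 241% of the microglial level, where RNA of their own cannot be told from free RNA. The others are genes of neurons and synapses, and these nuclei held them at 137%, 154%, 87.6% and 108% of the microglial level. At 1 wpi erythroid nuclei held pparg at 6.4%, trpv1 at 7.8%, robo4 at 12.4%, dnah3 at 13.2%, g0s2 at 21.1%, apoeb at 21.8% and tubb5 at 202% of it. The 12 named genes had the same sign in both batches, as the naming rule asks, with median sizes of 2.5 and 2.37. Within the batches dnah3 stood at 3.45 and 4.44, apoeb at 1.32 and 1.69 and pparg at 1.41 and 0.99. Of 23 glutamate receptor genes 17 fell at 1 wpi adjusted over the list alone and 0 over all genes (camera adjusted p = 6.32e-16, and adjusted p = 0.157 with an estimated correlation). Of the 23 members 17 had an unadjusted p under 0.05 and DESeq2 called 4. The test called 0 genes between 1 and 3 wpi (1368 at an unadjusted p under 0.05, 16 by DESeq2) and 0 between 3 and 6 wpi (437, and 1 by DESeq2). Without either uninjured library the counts of 51, 0 and 9 became 0. Leaving out 1 wpi replicate 1 or 2, 3 wpi replicate 1 or 2, or 6 wpi replicate 1 or 2 gave 415, 69, 5, 11, 5 and 3 at 1 wpi, 198, 218, 0, 0, 0 and 0 at 3 wpi, and 159, 196, 3, 2, 1 and 0 at 6 wpi. There were 4 and 618 calls between 1 and 3 wpi without 1 wpi replicates 1 and 2. With only the 4 libraries of the contrast the counts were 0 at 1 wpi and 226 at 3 wpi, and with no doublets removed 17 at 1 wpi. With only nuclei of at least 1000 UMIs they were 15 and 5 at 1 and 6 wpi, and with the batch as a term 319 at 1 wpi. With the replicate number as a block more genes were called at each time, as given below.

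Summed over all nuclei, whole libraries gave 198 higher and 19 lower genes at 1 wpi among 26,332 tested, 23 and 0 at 3 wpi, and 70 and 0 at 6 wpi, which mix changes within classes with changes in the classes' shares. At 3 and 6 wpi 4206 and 3371 genes had an unadjusted p under 0.05, and DESeq2 called 876 and 824. Between 1 and 3 wpi and between 3 and 6 wpi the test called 0 genes (2096 and 519 at an unadjusted p under 0.05, 30 and 0 by DESeq2). The counts of 217, 23 and 70 became 0 without either uninjured library and without any 1 library of 3 or 6 wpi, 2533, 318 and 276 without 1 wpi replicate 1, and 8, 102 and 245 without 1 wpi replicate 2. They were 0 at each time with the batch as a term and without both libraries of the shorter gene list.

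The shares of the cell classes ask whether the makeup of the kept nuclei differed. Microglia and macrophages made up 5.04% ± 0.681 of nuclei in uninjured cord (SD, n = 2), 16.0% ± 5.07 at 1 wpi, 13.6% ± 0.852 at 3 wpi and 8.33% ± 3.2 at 6 wpi. Neurons made up 30.8% ± 3.02, 20.3% ± 3.60, 28.1% ± 0.96 and 24.4% ± 2.64, and ependymo-radial glia 11.6% ± 5.73, 10.4% ± 0.675, 17.4% ± 1.18 and 17.2% ± 2.35. No share passed the test: edgeR called 0 of 35 class and contrast pairs after adjustment, with 7 at an unadjusted p under 0.05 and no other tool for counts run. The lowest adjusted p was 0.0816, for microglia at 1 wpi (log2 ratio 1.67 ± 0.36), microglia at 3 wpi (1.43 ± 0.36) and fibroblasts at 3 wpi (1.27 ± 0.30), and neurons at 1 wpi had adjusted p = 0.172 (-0.60 ± 0.22). An exact permutation test of the F statistic over all partitions of the 8 libraries into pairs gave p = 0.019 for fibroblasts, 0.0381 for neurons, 0.0381 for oligodendrocyte precursors and 0.0476 for microglia, all at an adjusted p of 0.0833 over the 7 classes. Between 1 wpi and uninjured cord the microglial share was 12.4% against 5.52% in the batch of the shorter gene list and 19.6% against 4.55% in the other, and the neuronal share 17.8% against 32.9% and 22.9% against 28.7%. With clusters at the lower resolution microglia at 1 wpi passed at an adjusted p of 0.0493. With the replicate number as a block some shares also passed, as given below. Clusters without a name, whose share differed between libraries of 1 group, are outside these classes but enter the totals. Cluster 5, led by the vitellogenin gene vtg1, held 22.0% and 10.4% of the uninjured libraries and at most 2.12% of any library after transection. Cluster 9, with the egg-coat gene zp3 among its leading genes, held 6.81% and 6.26% of the uninjured libraries and 7.75% and 0% at 1 wpi. The class shares can therefore depend on nuclei that may not be of the cord.

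**Figure D3:**
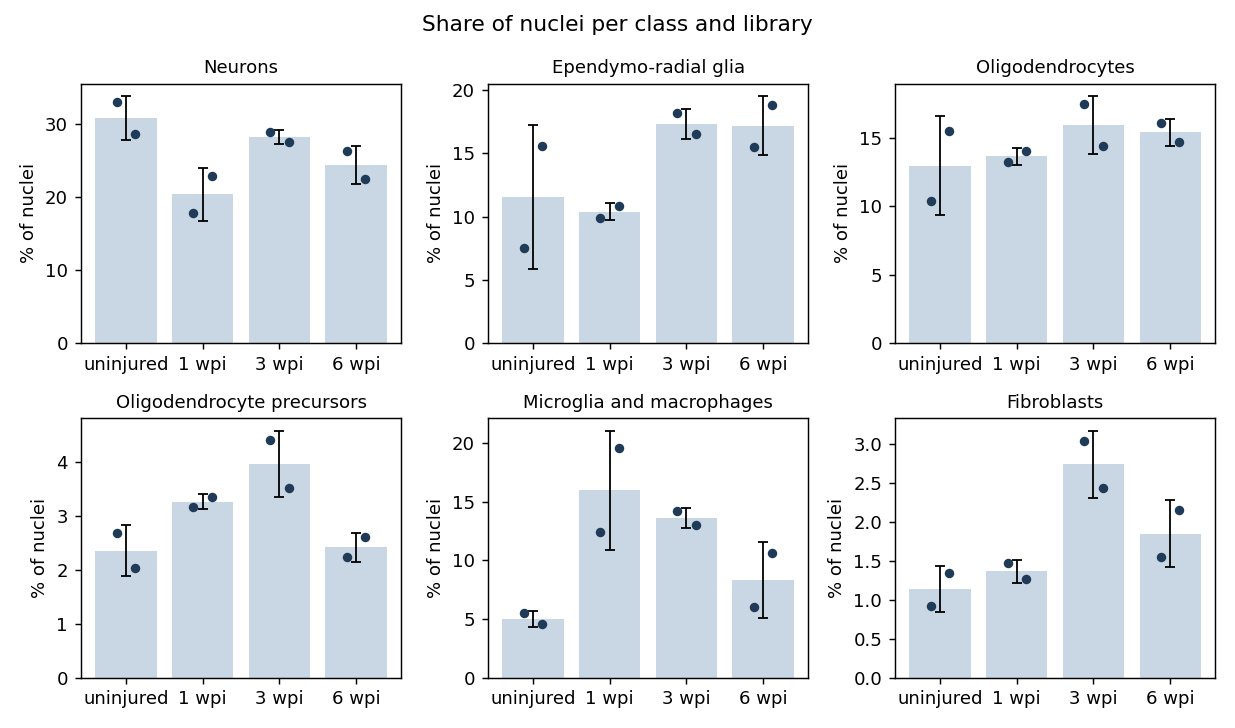
Share of nuclei (vertical axis, percent of all kept nuclei) of 6 cell classes in each group (horizontal axis). Bars are means, error bars the SD and points the 2 libraries of a group, and microglia with macrophages stood at 16.0% at 1 wpi against 5.04% in uninjured cord.

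The excitatory share of transmitter RNA asks whether the balance of excitatory and inhibitory neurons differed. Among UMIs of the glutamate transporter genes slc17a6a and slc17a6b and of the inhibitory genes gad1b, gad2, slc32a1 and slc6a5 in neurons, those of the glutamate transporter genes made up 14.3% ± 0.905 in uninjured cord (SD, n = 2) and 20.2% ± 0.647 at 1 wpi. They made up 14.2% ± 1.77 at 3 wpi and 16.8% ± 0.822 at 6 wpi, from 2710 to 6899 UMIs per library. Within batches it was 20.7% at 1 wpi (95% Wilson interval 19.6% to 21.8%) against 13.6% (12.7% to 14.6%), and 19.8% (18.5% to 21.1%) against 14.9% (14.1% to 15.8%), intervals that cover counting error only. The groups differed by more than their libraries, at F = 12.7 and p = 0.0476 in the exact permutation test over all partitions. The difference of 1 wpi from uninjured cord was 5.94 percentage points, and it lay between 5.30 and 6.58 with 1 library left out. With nuclei thinned to 1000 UMIs the difference was smaller, at 17.2% against 14.3%. Among the genes of this share slc6a5 stood at 197 against 342 CPM, which was not called (adjusted p = 0.178), while slc17a6a stood at 37.0 against 29.8 and slc17a6b at 58.0 against 59.9 CPM. Of the 6 genes slc6a5, a gene of glycinergic neurons, had the largest difference. Its log2 fold change at 1 wpi was -0.80 in neurons. By edgeR it was -1.75 in oligodendrocytes (adjusted p = 0.0293), -1.50 in ependymo-radial glia (adjusted p = 0.0316) and -1.35 in microglia (adjusted p = 0.0659). It is also among the leading genes of neuron clusters 4 and 11. Whether its fall arose in neurons was not tested. As a share of nuclei the test gave p = 0.2, with nuclei thinned to 1000 UMIs p = 0.0762 and with no doublets removed p = 0.0571, all exact.

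The cycling share asks whether more ependymo-radial glia were dividing. Nuclei thinned to 1000 UMIs with at least 2 of 47 cell cycle genes made up 19.2% ± 15.5 of the glia in uninjured cord (SD, n = 2), 24.7% ± 26 at 1 wpi, 4.76% ± 2.31 at 3 wpi and 4.53% ± 2.68 at 6 wpi. The libraries of 1 group differed by more than the groups (F = 0.9, p = 0.314, exact permutation test over all partitions). The batch of the shorter gene list gave 43.0% at 1 wpi (95% Wilson interval 40.3% to 45.7%) against 30.1% (26.4% to 34.1%), and the other batch 6.29% (4.79% to 8.22%) against 8.18% (6.75% to 9.88%). Oligodendrocytes, which do not divide, gave 22.4% ± 20.6, 19.3% ± 25.1, 2.26% ± 0.495 and 3.47% ± 3.86 in the same groups. The glial share less that of the oligodendrocytes was -6.87 and 0.37 percentage points in the uninjured libraries, 5.96 and 4.71 at 1 wpi, 3.78 and 1.21 at 3 wpi, and 0.23 and 1.90 at 6 wpi, a difference that was not tested. The proliferation marker gene mki67 was not called in these glia, with log2 fold changes of 0.59 ± 0.73, -0.52 ± 0.76 and -1.33 ± 0.78 (adjusted p = 0.811, 0.763 and 0.560). Shallower glia left out numbered 0 and 41 in uninjured cord, 3 and 12 at 1 wpi, 456 and 56 at 3 wpi, and 1 and 24 at 6 wpi. Without thinning the shares were 41.2% ± 26.4, 45.9% ± 46.1, 8.55% ± 1.56 and 12.1% ± 5.86 (exact p = 0.257). The difference of 1 wpi from uninjured cord was 5.50 percentage points and became -12.9 without 1 wpi replicate 1, 23.9 without 1 wpi replicate 2, 16.5 without uninjured replicate 1 and -5.47 without uninjured replicate 2.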

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

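The ratio of 2 over the highest uninjured library, by which the clusters below stand out, was chosen only after the data were seen. These clusters carry no cell name and are outside the comparisons of the report, and each made up more than 2 times the share of nuclei of any uninjured library. Cluster 3, whose leading genes include the titin gene ttn.2, the hemoglobin gene hbba1 and ache, made up 16.7% of nuclei at 6 wpi against at most 1.11% in an uninjured library. Its share differed widely within groups, at 0.008% and 11.7% in the libraries of 1 wpi, 0.87% and 6.23% at 3 wpi, and 19.4% and 14.0% at 6 wpi. Cluster 22, led by the Notch ligand genes dla and dlc with ebf2, robo3, notch1b and gadd45gb.1, made up 2.72% at 3 wpi against at most 0.827%. Cluster 42, led by matk, rxrga, pparg, gpnmb and spp1, made up 0.349% at 3 wpi and 0.368% at 6 wpi against at most 0.014%. Its share was higher at 1 wpi, at 2.02% and 0.673% of the 2 libraries. It was not flagged there because 5 of its leading genes were themselves called in whole libraries. This cluster scored highest for microglia but is outside the microglial class. Cluster 45, led by the antiviral genes dhx58, stat1b, rsad2 and helz2, made up 0.682% at 1 wpi (0.291% and 1.07% in the 2 libraries) against at most 0.109%. No share of these clusters was tested. Groups of 2 libraries are too small for a rule on samples far from the others, and no effect was tested as differing between groups.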

How the results depend on the processing

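The alternatives chosen only after the results were seen were the batch of the gene list length as a term, leaving out both libraries of the shorter list, leaving out nuclei over 20,000 UMIs, and shares among named classes only. No called result turned its direction under any alternative run, and the cycling difference of 1 wpi, which was not called, changed sign with 1 library left out. Of the repeats of counts and shares 302 stayed within 1.5 times the reported count or on the same side of the threshold, 231 moved and 3 lost the threshold. Of the repeats for named genes and list members, whether called or not, 6900 stayed on the same side of the threshold, 2098 lost a call and 112 gained one, and of those for gene lists 841 stayed, 284 lost and 27 gained a call. The direction of all 89 named genes held, and their calls held in 89 with DESeq2, 89 with no filter, 89 with the replicate block, 88 with the batch as a term, 81 with thinned counts and 76 with no doublets removed, but in 46 with nuclei of at least 1000 UMIs, 35 with only the 4 libraries of a contrast, 8 without uninjured replicate 1 and 11 without uninjured replicate 2. The naming rule asks for the same side in every library of a contrast, so a direction held with 1 library left out was all but fixed. With 2 libraries per group, the calls rest on the spread pooled over all groups, and where 1 library is left in a group it is assumed to vary like the others. The self-test missed most 2-fold changes and does not separate depth from the number of libraries, and at lower depth, with thinned counts, 8 of the 89 calls were lost. The reported counts were 47, 0 and 0 in neurons, 331, 298 and 191 in ependymo-radial glia, 183, 51 and 57 in oligodendrocytes, 51, 0 and 9 in microglia, and 217, 23 and 70 in whole libraries at 1, 3 and 6 wpi, and 0 between consecutive times. In the counts that follow, numbers are given for 1, 3 and 6 wpi against uninjured cord, then for 3 against 1 wpi and 6 against 3 wpi, and only where they moved by more than 1.5 times. Fewer libraries or fewer genes tested are the construction of some alternatives, and otherwise the cause was not tested.

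With 1 library left out, the count ran from 0 to 30, 0 to 0 and 0 to 3 in neurons, 0 to 320, 0 to 559 and 2 to 323 in ependymo-radial glia, 1 to 447, 1 to 206 and 1 to 138 in oligodendrocytes (0 to 5 for 3 against 1 wpi), 0 to 415, 0 to 218 and 0 to 196 in microglia and macrophages (0 to 618 for 3 against 1 wpi) and 0 to 2533, 0 to 318 and 0 to 276 in whole libraries. DESeq2's Wald test called 296, 133, 142, 35 and 1 genes in neurons, 701, 609, 462, 3 and 1 in ependymo-radial glia, 784, 259, 193 and 20 in oligodendrocytes (6 against 3 wpi stayed at 0), 299, 52, 45, 16 and 1 in microglia, and 1762, 876, 824 and 30 in whole libraries. With no filter on low counts the counts were 131, 7, 38 and 4 in neurons, 1208, 1656, 1224, 573 and 40 in ependymo-radial glia, 1297, 1284, 901, 627 and 39 in oligodendrocytes, 689, 733, 600, 564 and 38 in microglia, and 327 at 1 wpi in whole libraries. DESeq2's size factors gave 11 and 45 at 3 and 6 wpi in whole libraries. With only the 4 libraries of the contrast the count at 1 wpi was 0 in all 4 classes and in whole libraries, those at 3 wpi were 661 in ependymo-radial glia, 560 in oligodendrocytes, 226 in microglia and 2388 in whole libraries, and those at 6 wpi 20, 36 and 0 in ependymo-radial glia, oligodendrocytes and whole libraries.

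With nuclei of at least 1000 UMIs the counts were 1 at 6 wpi in neurons, 67, 0 and 1 in ependymo-radial glia, 53 at 1 wpi in oligodendrocytes, 15 and 5 at 1 and 6 wpi in microglia, and 33, 8 and 25 in whole libraries. With no doublets removed they were 2 at 6 wpi in neurons, 17 at 1 wpi in microglia and 389 at 1 wpi in whole libraries. At the lower clustering resolution they were 1 at 3 wpi in neurons and 92 at 1 wpi in microglia. Among genes with at least 20% of the level of the highest class they were 78 and 3 at 1 and 3 wpi in neurons, 671, 565 and 403 in ependymo-radial glia, 791 and 96 at 1 and 3 wpi in oligodendrocytes, and 371, 4 and 5 in microglia. Thinned counts gave 85 and 4 at 1 and 3 wpi in microglia. With the batch as a term the counts were 1.1e+02 (82 higher and 23 lower) and 1 at 1 and 6 wpi in neurons, 773 and 298 at 1 and 6 wpi in ependymo-radial glia, 973 at 1 wpi in oligodendrocytes, 319 at 1 wpi in microglia, and 0, 0 and 0 in whole libraries. Without both libraries of the shorter gene list they were 0 at 1 wpi in neurons, 21, 107 and 50 (1 for 3 against 1 wpi) in ependymo-radial glia, 1.1e+02 (40 higher and 65 lower), 1 and 2 (5 for 3 against 1 wpi) in microglia, and 0, 0 and 0 in whole libraries. Without nuclei over 20,000 UMIs they were 1 at 6 wpi in neurons and 642, 45 and 118 in whole libraries. Of the 288 list tests 162 passed with the preset correlation, 3 with an estimated one, 66 by the rotation test fry and 167 with the batch as a term. The count of 0 called class shares became 1 at the lower resolution, and stayed at 0 with TMM factors, with shares of neurons, glia and oligodendrocyte lineage, with shares among named classes, with the batch as a term and with any 1 library left out. The excitatory share had exact p = 0.2 as a share of nuclei, 0.0762 with thinned nuclei (17.2% at 1 wpi against 14.3%) and 0.0571 with no doublets removed.

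The replicate numbers were checked for pairing through the correlation across 26,332 genes of the deviations from the group means. Libraries with the same number correlated at 0.175 between uninjured cord and 1 wpi, 0.0469 between uninjured cord and 3 wpi, and 0.258, 0.467, 0.719 and 0.433 between the other groups. Since 1 pair lay under 0.1, the numbers were not taken to pair the libraries, although all these correlations were positive. With 2 libraries per group the deviations mirror each other, so every library then correlates better with those of its own number. A structure shared by libraries of the same number is therefore not excluded. With the replicate number as a block the counts were 315, 38, 79 and 1 in neurons, 1336, 1321, 907 and 9 in ependymo-radial glia, 1786, 689, 398 and 7 in oligodendrocytes, 569, 30, 42 and 1 in microglia (6 against 3 wpi stayed at 0 in each), and 1037, 286 and 358 in whole libraries, 155 list tests passed, and 6 class shares were called. In oligodendrocyte precursors the block gave 1015, 218 and 29 calls at 1, 3 and 6 wpi, and in fibroblasts 296, 186 and 143.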

Other observations

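The tests chosen only after the result was seen were those of the gene lists in oligodendrocyte precursors and fibroblasts, of dilution by larger oligodendrocyte nuclei and of the receptors within oligodendrocytes. Oligodendrocyte precursors, the dividing glia that give rise to oligodendrocytes, had 183 genes higher and 269 lower at 1 wpi among 10,297 tested (edgeR, 1973 at an unadjusted p under 0.05). The growth factor receptor gene egfra rose from 411 ± 77.1 to 1151 ± 78.3 CPM (SD, n = 2; log2 fold change 1.49 ± 0.20 SE, adjusted p = 0.00744), the adhesion gene l1cama from 529 ± 13.6 to 2271 ± 277 CPM (2.1 ± 0.24, adjusted p = 0.00631), and the transcription factor gene stat3 from 140 ± 22.2 to 491 ± 117 CPM (1.81 ± 0.29, adjusted p = 0.0115). The myelin transcription factor gene myrf rose from 354 ± 54.1 to 870 ± 2.26 CPM (1.30 ± 0.20, adjusted p = 0.00877), 1 of the 2 myelin genes of 14 that rose, and the coactivator gene wwtr1 from 9.03 ± 6.69 to 128 ± 22.0 CPM (3.83 ± 0.51, adjusted p = 0.00724). Of 23 glutamate receptor genes 6 fell, among them grm5b (-1.69 ± 0.24, adjusted p = 0.00744) and gria3b (-0.87 ± 0.19, from 1205 ± 147 to 659 ± 90.2 CPM, adjusted p = 0.033), and 18 fell adjusted over the list alone (camera adjusted p = 1.92e-12, and adjusted p = 0.113 with an estimated correlation). Of 20 GABA and glycine receptor genes 6 fell and of 34 voltage-gated channel genes 5 (camera adjusted p = 1.37e-08 and 1.4e-09, and adjusted p = 0.0295 for each with an estimated correlation). Within the batches of the shorter and longer gene list, egfra differed by 1.74 and 1.29 in log2(CPM + 1), l1cama by 2.23 and 2.00, and grm5b by -1.64 and -1.67. Erythroid nuclei held egfra at 12.7%, l1cama at 12.7%, myrf at 12.3%, wwtr1 at 44.8% and stat3 at 76.2% of the precursor level at 1 wpi, and gria3b at 72.2% and grm5b at 60.4% in uninjured cord. The count of 452 became 69 and 91 without uninjured replicates 1 and 2, 316 and 213 without 1 wpi replicates 1 and 2, 181 and 220 without those of 3 wpi and 254 and 265 without those of 6 wpi, and 902 with the batch as a term. At 3 and 6 wpi 0 and 1 genes were called (1288 and 642 at an unadjusted p under 0.05, 71 and 8 by DESeq2). These counts became 93 and 22 without 1 wpi replicate 1, 83 and 2 without 1 wpi replicate 2, 2 and 0 without 6 wpi replicate 1, 2 and 1 without 6 wpi replicate 2 and 0 each without any other library, and the count at 3 wpi became 7 with the batch as a term.

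Fibroblasts had 47 genes higher and 11 lower at 1 wpi among 7155 tested (1111 at an unadjusted p under 0.05, 128 by DESeq2). The N-cadherin gene cdh2 rose from 230 ± 2.32 to 674 ± 22.4 CPM (SD, n = 2; 1.55 ± 0.29, adjusted p = 0.0367) and the matrix link gene hapln1b from 12.9 ± 18.2 to 169 ± 41.8 CPM (3.47 ± 0.68, adjusted p = 0.0418), the 1 of 29 matrix genes that rose (camera adjusted p = 0.000372, and adjusted p = 0.384 with an estimated correlation). Within batches cdh2 differed by 1.41 and 1.48 and hapln1b by 6.88 and 2.81, and erythroid nuclei held them at 49.8% and 27.1% of the fibroblast level. The count of 58 became 6 and 0 without uninjured replicates 1 and 2, 127 and 79 without 1 wpi replicates 1 and 2, 25 and 24 without those of 3 wpi and 87 and 82 without those of 6 wpi, and 170 with the batch as a term. At 3 and 6 wpi 5 and 3 genes were called (860 and 793 at an unadjusted p under 0.05, 34 and 31 by DESeq2), which became 0 and 2 without uninjured replicate 1, 0 each without uninjured replicate 2, 152 and 116 without 1 wpi replicate 1, 173 and 118 without 1 wpi replicate 2, 0 and 3 without either library of 3 wpi, 28 and 17 without 6 wpi replicate 1, 22 and 2 without 6 wpi replicate 2, and 2 and 9 with the batch as a term.

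The cell cycle list was lower at 3 and 6 wpi in all 4 main classes, including neurons at 3 wpi (median log2 fold change -1.39, camera adjusted p = 1.37e-07) and oligodendrocytes, which do not divide (-1.96 and -1.73, camera adjusted p = 3.01e-05 and 1.6e-07), with adjusted p from 0.531 to 0.670 with an estimated correlation in these. A candidate explanation is RNA of egg cells in the droplets, since over the 8 libraries the CPM of cell cycle genes in oligodendrocytes followed that of 21 egg genes (Spearman rho = 0.976, exact permutation p = 0.0004, adjusted p = 0.0008 over 4 relations, and Pearson r = 0.992, exact permutation p = 7e-05, adjusted p = 0.00014, with r = 0.976 without the 2 libraries farthest from the median). In oligodendrocytes the egg genes stood at 3493 and 890 CPM in the uninjured libraries, 2785 and 33.3 at 1 wpi, 323 and 146 at 3 wpi, and 655 and 179 at 6 wpi. A change in the share of dividing ependymo-radial glia cannot be told apart, since 0 of the 4 libraries of 3 and 6 wpi lay below both uninjured libraries once the share in oligodendrocytes was taken off, but none could have: the shares taken off were 2.61%, 1.91%, 6.20% and 0.739%, and the lower uninjured difference was -6.87 percentage points.

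Genes of neurons were lower at 1 wpi in classes that are not neurons. Less free RNA from neurons stays open: 26 genes highest in neurons and low in oligodendrocytes had a median log2 fold change of -0.77 there (quartiles -1.0 and -0.45), and neurons held 32.1% and 35.1% of UMIs against 48.1% and 47.0% in uninjured cord. Against it, neurons held as little at 6 wpi (33.1% and 37.0%), while the median of such genes was then -0.22 in oligodendrocytes, -0.05 in ependymo-radial glia and 0.12 in microglia. Dilution in oligodendrocyte nuclei with more UMIs cannot be told apart, since UMIs of these genes per nucleus fell by 0.522 on the log2 scale, but from 5037 and 3147 to 2507 and 3191 per 1000 nuclei, so that the spread between the uninjured libraries is as wide. A fall of receptor RNA within oligodendrocytes also stays open, as 23 glutamate receptors lay at -1.06 and 25 other genes highest in neurons at -0.74, a difference of -0.328 that lies between the bounds set for either reading.

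The tubulin gene tubb5 was higher at 1 wpi in neurons, ependymo-radial glia, microglia and oligodendrocytes. Free RNA is a candidate explanation, because erythroid nuclei of the 2 libraries of 1 wpi held tubb5 at 301 and 387 CPM, at least 245.4% of the level in neurons of the same library, from 43 and 68 UMIs. These CPM do not allow for depth. In 1 wpi replicate 1 tubb5 had 43 UMIs in 100 erythroid nuclei and 1405 in 2322 neurons. In replicate 2 it had 68 in 179 and 864 in 1666, so that erythroid nuclei held no more of it per nucleus. For mixed nuclei, the rise in neurons changed by 0.012 on the log2 scale when no doublets were removed. This cannot decide the question, because only 7.8% of barcodes had been removed as doublets. Mixed nuclei that the removal missed stayed in both counts. Which cells made this RNA stays open, and an induction of tubb5 by the injury in some of them was not tested.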
